A study of Homo sapiens with 26 samples.

How the data were processed

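Single-cell RNA sequencing had been run on live CD45+ cells sorted from mucosal biopsies, with 1 library for each of 26 labelled samples: 5 of uninflamed ileal pouch, 10 of pouchitis and 11 of inflamed ulcerative colitis (UC) taken from the rectum. Biopsies were frozen, thawed, digested with collagenase VIII and DNase, sorted, and made into libraries with the 10x Genomics Single Cell 3′ chemistry, version 2. The submitters' processing notes name Cell Ranger, with no version, and the genome build GRCh38. Reads were not used here.

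The combined matrix deposited by the authors holds natural log values, ln(1 + 10000 × count / total), for 25332 gene symbols in 55931 cells. The authors' cell table adds the total UMI counts and the number of genes per cell, the percent of mitochondrial counts, and 6 major and 22 minor populations. Inverting the log with the deposited totals gave whole counts in all 93349731 entries above 0 (tolerance 1e-06), and the recovered totals and gene numbers equalled the deposited ones in all 55931 cells. The cells had been filtered before deposition: no kept cell had over 9.999% mitochondrial counts, under 503 UMIs or under 297 genes. Text files of each library were not used.

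Minor populations were grouped into T cells, B cells, plasma cells and myeloid cells. NK_cells and mast_cells were left out of these 4 classes, since their marker genes belong to none of them; they stayed in the denominator of shares. For 72 cells the major and minor populations gave different classes, and the minor one was used. Marker lists for cell types were written before the data were examined. UMIs were summed per library and class, so that a library and not a cell was the replicate, and a library entered a class fit with at least 20 cells of it.

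The libraries did not share a gene list. In 23 libraries (4 uninflamed pouch, 8 pouchitis, 11 inflamed UC) older gene symbols were counted and constant region genes of immunoglobulins and T cell receptors were not; in 3 libraries (1 uninflamed pouch, 2 pouchitis) newer symbols and those genes were counted. IGHG1, IGHA1, IGHD, IGHM, IGKC and TRAC had counts in 3 libraries and are listed at 0 in 23, so that they were not compared. Renamed symbols were joined through RefSeq synonyms (619 pairs with a log2 ratio of at most 3 between the tables; 16 pairs were not joined), which gave 24713 genes. A gene was then left out if it was at 0 in one table where at least 10 counts were expected, if the pouch libraries of both tables did not overlap and their medians differed over 4-fold, or if the medians differed over 16-fold at 20 CPM (UMIs of a gene scaled to a common library total of 1e6) or more. This removed 5570 genes, which held 1.348% of the UMIs of the 23 libraries and 17.078% of those of the 3. The rule was not planned. It went through 4 forms, revised after counts of called genes had been seen, because a chemokine paralog was called through the table difference and CXCL9 and INHBA were wrongly lost; the earlier forms left out 5961, 5498 and 5574 genes and stand among the alternatives. XIST, TSIX, Y chromosome genes (40 genes in all) and 210 variable, diversity and joining segments were also left out, which left 19101 genes. Of the gene symbols, 20535 were found in GENCODE 29, which gave identifiers and GRCh38 positions.

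Genes were tested with edgeR 4.0.16 (R 4.3.3): filterByExpr, TMM normalisation, and the quasi-likelihood F test on a model of 3 group means fitted to all libraries of a class. Adjusted p-values are Benjamini-Hochberg values over the genes of a class and contrast, with a threshold of 0.05; log2 fold changes are the fitted ones and carry standard errors (SE). CPM use TMM-scaled totals and are given as mean ± SD over libraries. The biological coefficient of variation was 0.246 in T cells, 0.338 in B cells, 0.263 in plasma cells and 0.333 in myeloid cells. Gene lists written before the data were examined were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the 43 tests of a contrast, and again with an estimated correlation. They were, in all classes, interferon response, immediate early and dissociation stress, NF-kB response, proliferation, gut homing and retention, epithelial, stromal and red cell markers, and mitochondrial transcripts; in T cells, regulatory T cell, cytotoxic, Th17 and type 3 cytokine, tissue residency, naive and central memory, and follicular helper and exhaustion lists; in B cells, germinal centre, naive, memory and MHC class II lists; in plasma cells, IgG, IgA and IgM, unfolded protein response and plasmablast lists; in myeloid cells, inflammatory monocyte, resident macrophage, dendritic cell, MHC class II, and neutrophil and mast cell lists. A list needed at least 3 tested members. Shares of cells were compared as the difference of mean percent by a two-sided permutation test, exact against the uninflamed pouch (3003 and 4368 splits) and with 100000 resamples between inflamed UC and pouchitis, adjusted over 26 populations. The smallest p that 100000 resamples can give is 1e-05.

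Named genes followed a rule fixed before the data were examined: in each class the 3 genes with the largest rise and the 3 with the largest fall among called genes with a mean of at least 20 CPM and at least 0.1 of the level of the class that expresses them most, the 3 members of smallest adjusted p of each list past the threshold, and a fixed set (IL1B, LYZ, S100A8, S100A9, C1QA, FOXP3, BATF, IL17A, GZMK, CCR9, GPR15 in their classes, IGHG1 and IGHA1 in plasma cells, IGHD in B cells); marker genes of epithelial, stromal and red cells, and immunoglobulin genes outside B and plasma cells, were passed over. Any gene named outside the rule is said to be so. Some genes that the rule names are not reported here.

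Total UMIs per library ran from 5315294 to 19187615 in inflamed UC, from 4088555 to 20364385 in pouchitis and from 12006554 to 21404789 in the uninflamed pouch. Counts were simulated with the group sizes, depth and spread of each class and with 200 changed genes. There 2-fold changes between pouchitis and the uninflamed pouch were recovered in 80% of genes in T cells, 56% in B cells and 74% in plasma cells. In myeloid cells 20% were recovered, and 84% at 4-fold. With fewer changed genes the adjusted threshold is stricter. These rates therefore do not show which changes were missed where 1 or 0 genes were called. Shares were simulated with an SD of 3 points for 10 against 5 libraries. Of 200 simulated populations without a change, 7.5% had p under 0.05 in the share test. Of those shifted by 8 points 99.5% had. Real shares had other SDs, such as 22.0 for B cells in pouchitis, so that rate does not show which share differences were missed. No pair of libraries within a group was a copy (110 pairs; smallest chi-square per degree of freedom 15.5). Free RNA and doublets could not be removed from these files: at least 2 UMIs of another class's markers were present in 27.8% of T cells, 10.1% of B cells, 35.7% of plasma cells and 61.8% of myeloid cells.

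Other settings fixed before the data were examined were another normalisation (RLE), no low-count filter, the replicate number as a block, depth as a covariate, at least 50 cells per library, leaving out doublet-like cells, only the most abundant population of a class, leaving out immunoglobulin genes, keeping variable segments, fitting only the 2 groups compared, DESeq2 1.42.0, other scales and denominators for shares, and leaving out each library. Those added after seeing the data were the gene tables as deposited, the 3 earlier forms of the rule, the 23 libraries of the larger table alone, the table as a covariate, leaving out the cycling population, and limma on log2 CPM with 3 counts added. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used for the rest.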

Results

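Leukocytes (CD45+ cells) sorted from intestinal biopsies were profiled by droplet single-cell RNA sequencing in 26 libraries. Of these, 5 came from uninflamed ileal pouches, 10 from pouches with pouchitis and 11 from the inflamed rectum in ulcerative colitis (UC). An ileal pouch is a reservoir built from small intestine after removal of the colon, and pouchitis is its inflammation. The deposited table held 16878 cells of the uninflamed pouch, 20678 of pouchitis and 18375 of inflamed UC. Cells per library had a median of 3489 in the uninflamed pouch (2275 to 4855), 2033 in pouchitis (1009 to 3707) and 1540 in inflamed UC (1140 to 2648). The median over libraries of the median UMIs per cell was 4246, 5606 and 5453 in the same order.

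T cells made up 60.0% ± 16.3 (SD, n = 5) of the cells of an uninflamed pouch library, 56.1% ± 16.4 (n = 10) in pouchitis and 51.0% ± 9.59 (n = 11) in inflamed UC. B cells made up 25.1% ± 11.9, 22.4% ± 22.0 and 21.02% ± 12.4, and plasma cells 10.7% ± 7.90, 12.7% ± 9.47 and 17.0% ± 8.59. Myeloid cells were few: 171 cells in the uninflamed pouch, where 4 libraries had at least 20, 1319 in pouchitis and 1429 in inflamed UC. The population names of the authors were kept. Among the top genes of Foxp3_cells were FOXP3, IL2RA and LAYN. Those of memory_CD8 held XCL1, IL2, CD160 and CCL3L1. Those of naive_CD8 held CD8B, CD160 and ITGA1, and those of mono_mac2 held IL1B, S100A9 and S100A8.

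Pouchitis was compared with the uninflamed pouch to ask which leukocytes and genes differ in the inflamed pouch. T cells of pouchitis carried more transcript of FOXP3, the transcription factor of regulatory T cells, at 32.0 ± 10.7 CPM (SD, n = 10) against 10.1 ± 3.63 CPM (n = 5). Other regulatory T cell genes were higher along with it, while edgeR called no gene in B, plasma or myeloid cells. Myeloid cells averaged 6.26% ± 3.80 of cells in pouchitis and 1.02% ± 0.379 in the uninflamed pouch. All 10 pouchitis libraries lay above the uninflamed mean, but this share did not pass the corrected test (exact permutation p = 0.00899, adjusted p = 0.0779).

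FOXP3 (ENSG00000049768.14, GRCh38 chromosome X, 49250436 to 49264826) was the 1 gene called among 10758 tested in T cells. Its log2 fold change was 1.65 (SE 0.29; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.041), and 10 of 10 pouchitis libraries lay above the uninflamed mean. The regulatory T cell list was higher in pouchitis (camera adjusted p = 6.7e-22; adjusted p = 0.038 with an estimated correlation). All 19 tested members were positive, with a median log2 fold change of 0.84. Of these members, 1 rose over all genes and 11 adjusted over the list alone. IL1R2, a decoy receptor for IL-1, stood at 17.5 ± 9.79 against 5.53 ± 2.90 CPM (adjusted p = 0.77), and IL2RA, the IL-2 receptor alpha chain, at 75.0 ± 19.7 against 38.1 ± 16.2 CPM (adjusted p = 1). Foxp3_cells made up 7.15% ± 2.06 of cells in pouchitis and 3.92% ± 0.954 in the uninflamed pouch (exact permutation p = 0.00733, adjusted p = 0.0779), higher in 9 of 10 libraries. Within Foxp3_cells the FOXP3 level was 197 ± 33.0 against 121 ± 29.4 CPM, a log2 fold change of 0.70 (SE 0.17).

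The Th17 and type 3 cytokine list was higher in pouchitis T cells (adjusted p = 1.6e-04; adjusted p = 0.80 with an estimated correlation). Of its 15 members 0 were called over all genes and 3 rose adjusted over the list alone. CCR6, a homing receptor of Th17 cells, stood at 145 ± 57.1 against 82.2 ± 9.72 CPM, and CTSH at 29.5 ± 9.56 against 15.9 ± 4.10 CPM, each above the uninflamed mean in 10 of 10 libraries. IL17A itself stood at 226 ± 120 against 253 ± 250 CPM. Its log2 fold change was -0.17 in all libraries and 0.69 among those of the larger gene table (adjusted p = 1 in both). The cytotoxic list was lower (adjusted p = 0.0039; adjusted p = 0.80 with an estimated correlation). Of its 20 members 0 were called over all genes and 1 fell adjusted over the list alone. GZMK, a granzyme of effector memory CD8 cells, stood at 103 ± 42.2 against 256 ± 149 CPM (adjusted p = 0.77), and IFNG at 508 ± 236 against 1046 ± 154 CPM, each below the uninflamed mean in 10 of 10 libraries. The immediate early and dissociation stress list was also lower (adjusted p = 2.0e-06; adjusted p = 0.80 with an estimated correlation). The NF-kB list was higher (adjusted p = 0.037; adjusted p = 0.80 with an estimated correlation). BATF was at 189 ± 86.5 against 124 ± 31.8 CPM and CCR9 at 21.8 ± 6.58 against 20.1 ± 4.31 CPM, both with an adjusted p of 1, and GPR15 had a log2 fold change of 0.52 (1.20 among the libraries of the larger gene table; adjusted p = 1 in both).

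In B cells of pouchitis the germinal centre list was lower (adjusted p = 2.5e-04; adjusted p = 0.80 with an estimated correlation), with a negative fold change in all 13 tested members. Their interferon list was higher (adjusted p = 0.011; adjusted p = 0.81 with an estimated correlation). The proliferation list was higher (adjusted p = 0.011; adjusted p = 0.86 with an estimated correlation). That direction turned when doublet-like cells were left out and when the cycling population was (adjusted p = 0.22 over the 10 lists of B cells). In myeloid cells the inflammatory monocyte list was higher (adjusted p = 3.0e-04; adjusted p = 0.80 with an estimated correlation). Its 31 members had a median log2 fold change of 0.85. THBS1 stood at 212 ± 208 against 32.8 ± 26.8 CPM (adjusted p = 0.74). SERPINB2 was at 25.98 ± 35.5 CPM against no count in the uninflamed pouch, at least 10.9-fold higher with a floor of 3 counts over the group. That bound covers counting only and not the spread between libraries. SERPINB2 had counts in 5 of 10 pouchitis libraries and was not called (adjusted p = 0.75). The myeloid NF-kB list was higher (adjusted p = 0.017; adjusted p = 0.80 with an estimated correlation). The MHC class II list was lower (adjusted p = 0.015; adjusted p = 0.80 with an estimated correlation). IL1B stood at 4036 ± 1495 against 4429 ± 1561 CPM and S100A8 at 546 ± 336 against 247 ± 131 CPM. The log2 fold changes of LYZ, S100A9 and C1QA were -0.15, 0.74 and -0.54, and the adjusted p of these 5 genes was at least 0.84. No plasma cell list was called.

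By edgeR 0 genes were called in B cells (199 at an unadjusted p under 0.05; 5 by DESeq2, 0 by limma), 0 in plasma cells (253; 1 by DESeq2, 0 by limma) and 0 in myeloid cells (491; 0 by DESeq2, 7 by limma). The FOXP3 call was lost under 7 other settings and without any 1 of the 5 uninflamed pouch libraries or any 1 of 6 pouchitis libraries. In these fits over all T cells the log2 fold change of FOXP3 was 1.52 to 1.76. Among the 23 libraries of the larger gene table it was 1.76 (SE 0.31) with an unadjusted p of 7.6e-06 against 3.8e-06 in all libraries.

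**Figure D1:**
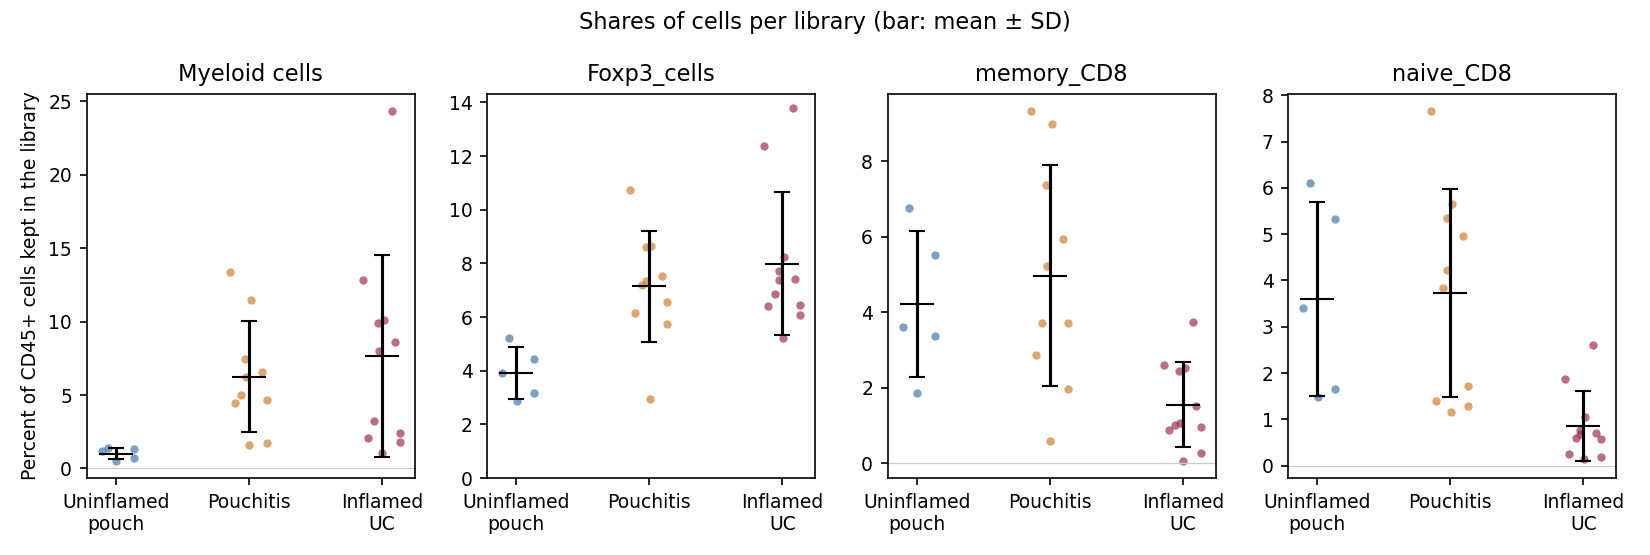
Percent of the CD45+ cells of each library (y axis) that were myeloid cells, Foxp3_cells, memory_CD8 or naive_CD8, by group (x axis); points are libraries and bars are means ± SD. Myeloid cells and Foxp3_cells averaged 1.02% and 3.92% in the uninflamed pouch, and memory_CD8 and naive_CD8 averaged 1.55% and 0.861% in inflamed UC, the lowest of the 3 groups in each panel.

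Inflamed UC was compared with the uninflamed pouch to ask how leukocytes of the inflamed rectum differ from those of a pouch without inflammation. T cells of inflamed UC carried more of the regulatory T cell genes FOXP3, CTLA4 and LAYN, and more of MAL, a gene of naive and central memory cells. They carried less of CCR9, the receptor that directs T cells to the small intestine, and less of genes of tissue-resident and cytotoxic cells (CD160, ITGA1, CD69, CCL5). The CD8 populations memory_CD8 (1.55% ± 1.13 against 4.22% ± 1.93) and naive_CD8 (0.861% ± 0.753 against 3.60% ± 2.10) had smaller shares. The top genes of naive_CD8 include CD160, ITGA1 and CCL5, so the authors' name was not read as naive cells. Myeloid cells carried less of CD1C and IFI30, genes of antigen presentation, and more of the solute transporter genes SLC16A10 and SLC7A11. The UC samples were from rectum and the pouch is ileal, so tissue and diagnosis changed together in every comparison with UC.

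In T cells 395 of 10758 genes were called, 196 higher and 199 lower. The regulatory T cell list was higher (adjusted p = 8.6e-18; adjusted p = 0.075 with an estimated correlation). Of 19 tested members 11 rose over all genes and 15 adjusted over the list alone. FOXP3 stood at 40.0 ± 16.3 CPM (SD, n = 11; log2 fold change 1.99, SE 0.29; edgeR adjusted p = 4.4e-04). CTLA4 stood at 213 ± 92.5 against 75.8 ± 17.3 CPM (1.49, SE 0.27; adjusted p = 0.0029) and LAYN at 23.9 ± 9.84 against 7.56 ± 2.55 CPM (adjusted p = 0.0040), each above the uninflamed mean in 11 of 11 libraries. Foxp3_cells made up 7.996% ± 2.66 of cells (exact permutation p = 0.00595, adjusted p = 0.0516), above the uninflamed mean in 11 of 11 libraries. Of 13 naive and central memory genes 4 rose over all genes and 5 adjusted over the list alone (list adjusted p = 0.0020; adjusted p = 0.43 with an estimated correlation). LEF1 rose by a log2 fold change of 1.43 (adjusted p = 0.037) and MAL by 1.06 (adjusted p = 0.017). TSHZ2 was among the 3 genes of largest rise, at 77.6 ± 49.5 against 23.7 ± 15.03 CPM (adjusted p = 0.044). The red cell list was not called (adjusted p = 0.18), but HBB, named outside the rule, rose by a log2 fold change of 4.86 (adjusted p = 0.047), and HBB and LEF1 were both among the top genes of memory_CD4.

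The follicular helper and exhaustion list was higher in T cells of inflamed UC (adjusted p = 0.0082; adjusted p = 0.43 with an estimated correlation; reversed within the most abundant T cell population). Of 16 members 2 rose, HAVCR2 (log2 fold change 1.71, edgeR adjusted p = 0.0040) and MAF (0.81, adjusted p = 0.036). CXCL13 had a log2 fold change of 1.97 (adjusted p = 0.28). Of 13 tissue residency genes 1 rose and 4 fell over all genes (2 and 5 adjusted over the list alone; list adjusted p = 3.8e-04; adjusted p = 0.39 with an estimated correlation). CD160 stood at 8.18 ± 6.66 against 56.1 ± 7.55 CPM (log2 fold change -2.84, SE 0.39; edgeR adjusted p = 2.4e-04). CD69 stood at 1815 ± 549 against 4037 ± 1246 CPM (adjusted p = 0.0034) and ITGA1 at 36.9 ± 24.2 against 117 ± 33.2 CPM (adjusted p = 0.0056). All of them lay below the uninflamed mean in 11 of 11 libraries. The cytotoxic list was lower (adjusted p = 0.0020; adjusted p = 0.43 with an estimated correlation). Of 20 members 2 fell, CCL5 at 818 ± 396 against 2159 ± 419 CPM (adjusted p = 0.0080) and CD8B (log2 fold change -1.07, adjusted p = 0.023). IFNG had -1.27 (adjusted p = 0.053) and GZMK -0.75 (adjusted p = 0.24). Whether these genes followed cell shares from library to library was not tested. The shares of memory_CD8 (exact permutation p = 0.00343, adjusted p = 0.0446) and naive_CD8 (exact permutation p = 0.00275, adjusted p = 0.0446) were smaller as well. Both shares lay below the uninflamed mean in 11 of 11 libraries, and the top genes of these populations include CD160, CD8B, ITGA1 and CCL5. Both share calls were lost in the 23 libraries of the larger gene table.

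CCR9 (ENSG00000173585.15, GRCh38 chromosome 3, 45886504 to 45903177) stood at 2.01 ± 1.48 against 20.1 ± 4.31 CPM in T cells (log2 fold change -3.34, SE 0.29; edgeR adjusted p = 2.7e-08), lower in 11 of 11 libraries. Its list, gut homing and retention, was not called (adjusted p = 0.097), and GPR15, a receptor that directs T cells to the colon, had a log2 fold change of -0.69 (adjusted p = 0.60), or -0.17 among the libraries of the larger gene table (adjusted p = 0.93). IL2 stood at 21.8 ± 19.96 against 181 ± 177 CPM (adjusted p = 0.018). The highest uninflamed pouch library reached 487 CPM of IL2 against a median of 105 in the others. CCL3L1, a near-identical paralog of CCL3, had a log2 fold change of -4.29 (adjusted p = 0.022). It was -1.22 among the libraries of the larger gene table, where its call was lost (adjusted p = 0.49). The log2 fold changes of BATF and IL17A were 0.83 (adjusted p = 0.087) and -0.11 (adjusted p = 0.95), and the Th17 list was not called (adjusted p = 0.54). IL17A turned in direction among the libraries of the larger gene table, at 0.66 (adjusted p = 0.68).

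The list of immediate early and stress genes, which respond to activation and to tissue digestion, was lower in inflamed UC in each class, each call lost with an estimated correlation. In T cells 11 of 27 fell over all genes and 20 adjusted over the list alone, with a median log2 fold change of -0.80 (adjusted p = 4.0e-18; adjusted p = 0.075 with an estimated correlation). NR4A1 stood at 225 ± 110 against 551 ± 133 CPM (edgeR adjusted p = 0.0063), DUSP1 had a log2 fold change of -0.89 (adjusted p = 0.016) and JUND one of -0.67 (adjusted p = 0.022). The list's adjusted p was 8.9e-09 in B cells, 1.3e-07 in plasma cells and 5.6e-12 in myeloid cells (adjusted p = 0.35, adjusted p = 0.35 and adjusted p = 0.11 with an estimated correlation). Over all genes 0 of 26 members fell in B cells and 0 of 26 in plasma cells. In myeloid cells 2 of 27 members fell over all genes, HSPE1 (log2 fold change -1.29, adjusted p = 0.016) and FOS (-1.13, adjusted p = 0.048), both lost among the libraries of the larger gene table. The NF-kB list was lower in T cells (adjusted p = 0.022; adjusted p = 0.43 with an estimated correlation). There 1 member rose and 2 fell, NFKBIE (-0.94, adjusted p = 0.012) and BCL2A1 (-1.31, adjusted p = 0.020). It was also lower in B cells (adjusted p = 3.0e-05; adjusted p = 0.35 with an estimated correlation). The interferon list was lower in T cells (adjusted p = 0.0095; adjusted p = 0.43 with an estimated correlation) and in plasma cells (adjusted p = 0.014; adjusted p = 0.43 with an estimated correlation). In T cells IFIT2 (-1.49, adjusted p = 0.0070) and IFI44L (-1.31, adjusted p = 0.0080) fell.

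B cells of inflamed UC had lower germinal centre genes as a list (adjusted p = 4.8e-06; adjusted p = 0.43 with an estimated correlation). All 13 members were negative, with a median log2 fold change of -0.61. The MHC class II list was lower in B cells (adjusted p = 0.0038; adjusted p = 0.43 with an estimated correlation), with HLA-DRA at -0.51 (adjusted p = 0.48). By edgeR 0 single genes were called in B cells (743 at an unadjusted p under 0.05; 10 by DESeq2, 0 by limma). NR4A1, BCL2A1 and CD83 had log2 fold changes of -0.91, -1.17 and -0.84 (adjusted p = 0.41, 0.34 and 0.47). In plasma cells 11 of 9305 genes were called, 5 higher and 6 lower. CCND2, a cyclin of the early cell cycle, stood at 120 ± 76.5 against 31.7 ± 7.78 CPM (edgeR adjusted p = 0.020), and CD69 at 343 ± 143 against 991 ± 415 CPM (adjusted p = 0.018). Each lay on 1 side of the uninflamed mean in 11 of 11 libraries. SMAP2 rose by a log2 fold change of 1.21 (adjusted p = 0.018), and INTS6 (-1.21, adjusted p = 0.037) and RARRES3 (-1.16, adjusted p = 0.018) fell. The unfolded protein response list was higher (adjusted p = 0.0030; adjusted p = 0.43 with an estimated correlation). Of its members 17 of 20 were positive and 0 were called over all genes, and XBP1, its secretory transcription factor, had a log2 fold change of 0.63 (adjusted p = 0.17).

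In myeloid cells 59 of 7381 genes were called, 23 higher and 36 lower, with n = 10 against n = 4 libraries. SLC16A10 stood at 118 ± 93.0 CPM against no count, at least 49.6-fold higher with a floor of 3 counts over the pooled group. That bound covers counting only and not the spread between libraries. SLC7A11, the cystine transporter, stood at 167 ± 155 against 6.88 ± 5.51 CPM (edgeR adjusted p = 0.046). HS3ST3B1 had 382 counts against 1, a ratio of 34.8 per total with a 95% counting interval of 6.21 to 1378. CD1C, which presents lipids on dendritic cells, stood at 37.0 ± 30.1 against 228 ± 54.3 CPM (edgeR adjusted p = 0.0090), lower in 10 of 10 libraries. CLEC11A (log2 fold change -2.07, adjusted p = 0.016) and WDFY2 (-1.80, adjusted p = 0.017) also fell. Among the libraries of the larger gene table CD1C kept its call. Those of SLC16A10, SLC7A11, HS3ST3B1, CLEC11A and WDFY2 were lost there (adjusted p = 0.11, 0.14, 0.059, 0.12 and 0.26), with WDFY2 at -0.89. The MHC class II list was lower (adjusted p = 4.0e-07; adjusted p = 0.16 with an estimated correlation). IFI30 fell to 287 ± 82.6 from 676 ± 282 CPM (adjusted p = 0.016), 9 of 12 members fell adjusted over the list alone, and HLA-DRA had -0.67 (adjusted p = 0.061). The inflammatory monocyte list was higher (adjusted p = 4.8e-07; adjusted p = 0.43 with an estimated correlation). Of 31 members 0 were called over all genes and 14 rose adjusted over the list alone. THBS1 had 4.17 (adjusted p = 0.054) and VCAN 2.08 (adjusted p = 0.090). S100A8 (2.01) and S100A9 (1.82) each had an adjusted p of 0.22, and IL1B (-0.14), LYZ (-0.19) and C1QA (0.06) one of at least 0.84. Myeloid cells made up 7.67% ± 6.88 of cells in inflamed UC, above the uninflamed mean in 11 of 11 libraries. This did not pass the corrected test (exact permutation p = 0.0321, adjusted p = 0.141).

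Among the 23 libraries of the larger gene table the calls were 206 in T cells, 2 in plasma cells and 3 in myeloid cells. In T cells those of LEF1, TSHZ2, MAF, BCL2A1 and JUND were lost there (adjusted p = 0.11, 0.12, 0.058, 0.056 and 0.070), as were those of the 5 called plasma cell genes named above. Without 1 of 3 uninflamed pouch libraries T cell calls were 130, 185 or 214. Without 1 library plasma cell calls ranged from 1 to 34 and myeloid calls from 2 to 256.

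**Figure D2:**
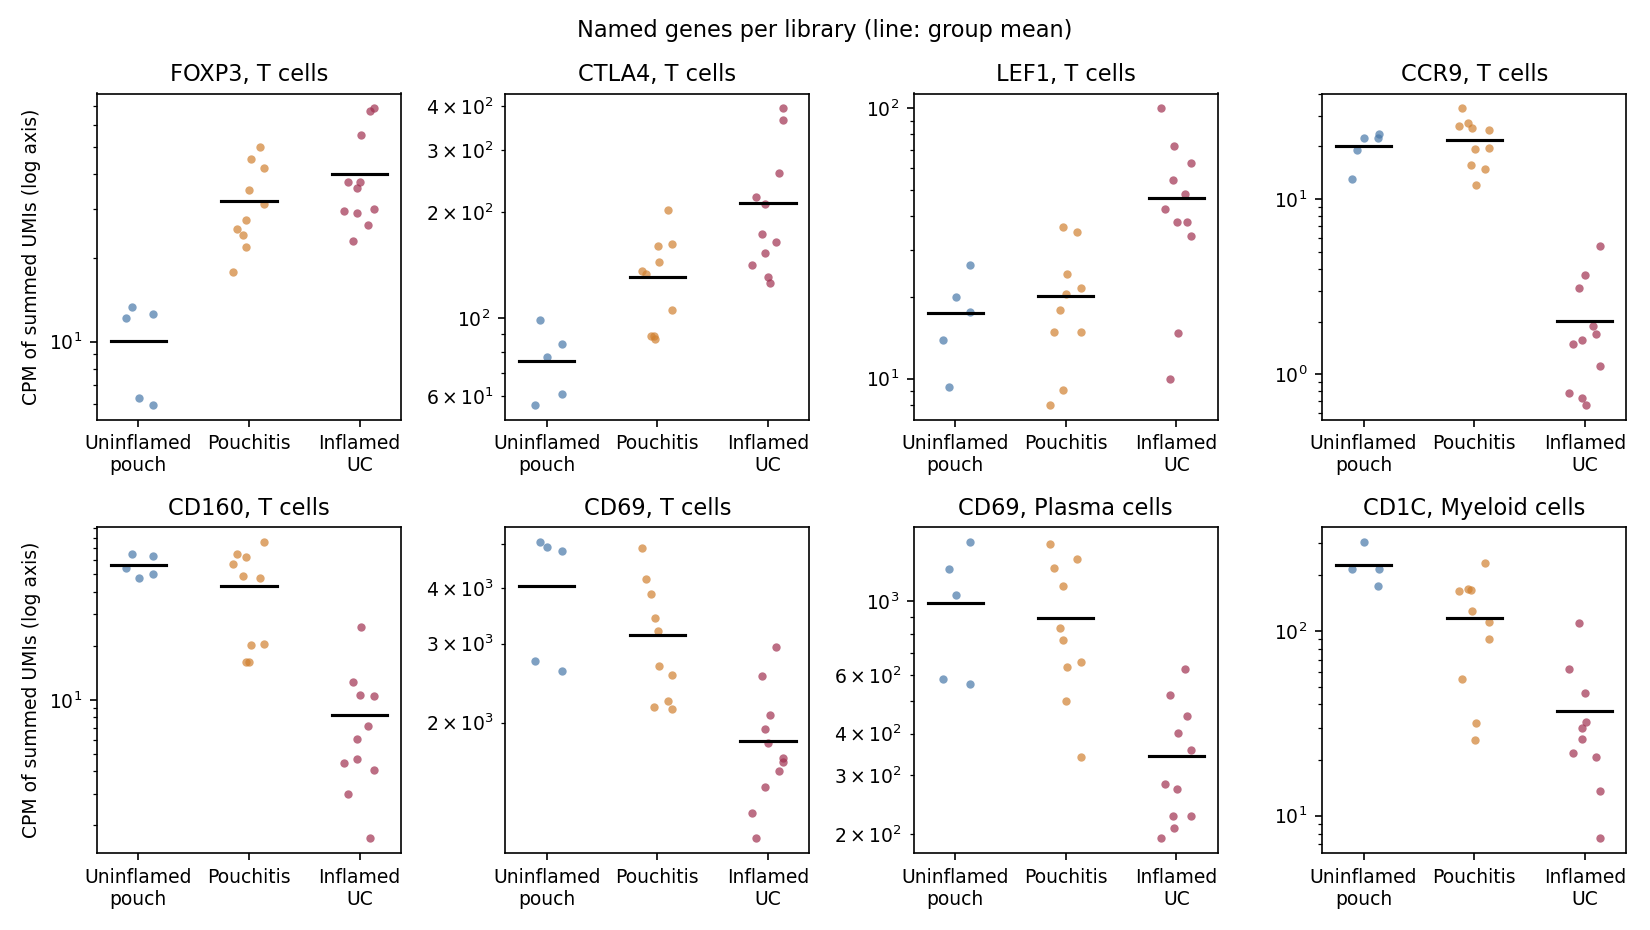
CPM of summed UMIs (y axis, log scale; values under 0.3 drawn at 0.3) of 7 named genes in the class given above each panel, by group (x axis); points are libraries and lines are group means. In T cells CCR9 averaged 20.1 CPM in the uninflamed pouch, 21.8 in pouchitis and 2.01 in inflamed UC, and FOXP3 averaged 10.1, 32.0 and 40.0 CPM.

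Inflamed UC was compared with pouchitis to ask how inflammation of the rectum and of the pouch differ. T cells of inflamed UC carried more CXCL13, the chemokine that attracts B cells to follicles, at 97.7 ± 113 against 8.43 ± 10.0 CPM. They carried less CCR9 (log2 fold change -3.48, SE 0.26), CD160 (-2.46), IL2 (-3.16) and XCL1 (-2.77), and the shares of memory_CD8 and naive_CD8 were smaller. The pouchitis libraries highest in IL2 and XCL1 stood apart, at 1058 and 1358 CPM against medians of 87.8 and 107 in the others. Plasma cells carried more of the secretory gene PRDX4, and myeloid cells more of CXCL5, a neutrophil chemokine, and CD163, a scavenger receptor of macrophages. FOXP3 was not called (log2 fold change 0.34, edgeR adjusted p = 0.47).

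In T cells 231 of 10758 genes were called, 95 higher and 136 lower. CCR9 (edgeR adjusted p = 9.9e-10) and ITGB7 (log2 fold change -0.61, adjusted p = 0.031), the integrin chain of gut homing, fell, each lower in 11 of 11 libraries. Their list was lower (adjusted p = 0.0039; adjusted p = 0.20 with an estimated correlation). GPR15 had -1.21 (adjusted p = 0.23). Of 13 tissue residency genes 5 fell over all genes and 6 adjusted over the list alone (list adjusted p = 7.2e-09; adjusted p = 0.12 with an estimated correlation). Among them were CD160 (8.18 ± 6.66 against 42.9 ± 22.7 CPM, adjusted p = 4.1e-04), ITGA1 (-1.66, adjusted p = 0.0032) and CD244 (-1.18, adjusted p = 0.0032). IL2 (adjusted p = 0.0095) and XCL1 (adjusted p = 0.018), whose near-identical paralog is XCL2, fell in 11 of 11 libraries. The share of memory_CD8 was smaller as well, 1.55% ± 1.13 against 4.97% ± 2.94 (permutation p = 0.00131, adjusted p = 0.0170). So was that of naive_CD8, 0.861% ± 0.753 against 3.73% ± 2.25 (permutation p = 6.3e-04, adjusted p = 0.0164). Both lay below the pouchitis mean in 11 of 11 libraries. The cytotoxic list was not called (adjusted p = 0.17).

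The follicular helper and exhaustion list was higher (adjusted p = 1.2e-05; adjusted p = 0.24 with an estimated correlation; reversed within the most abundant T cell population). Of 16 members 2 rose, CXCL13 (log2 fold change 3.60, SE 0.84; edgeR adjusted p = 0.019; 10 of 11 libraries) and HAVCR2 (1.03, adjusted p = 0.023). Tfh_cells made up 8.37% ± 3.12 of cells against 6.03% ± 1.80 (permutation p = 0.0510, adjusted p = 0.442). Of the naive and central memory genes 3 rose, among them LEF1 (1.23, adjusted p = 0.028) and MAL (0.78, adjusted p = 0.028), and TSHZ2 rose as well (1.51, adjusted p = 0.028). The list had an adjusted p of 0.0064 (adjusted p = 0.45 with an estimated correlation). The regulatory T cell list was higher (adjusted p = 2.3e-04; adjusted p = 0.39 with an estimated correlation). Of its members 0 were called over all genes and 3 rose adjusted over the list alone. CTLA4 had 0.70 (adjusted p = 0.063) and LAYN 0.82 (adjusted p = 0.066). The Th17 list was lower (adjusted p = 0.019; adjusted p = 0.58 with an estimated correlation), with IL17A at 0.05 (adjusted p = 0.98). BATF and GZMK had 0.23 and 0.56 (adjusted p = 0.65 and 0.34). Red cell transcripts were higher in T cells of inflamed UC (list adjusted p = 0.048; adjusted p = 0.39 with an estimated correlation). HBB stood at 39.5 ± 86.7 against 1.10 ± 0.719 CPM (edgeR adjusted p = 0.010), above the pouchitis mean in 5 of 11 libraries.

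As lists, stress and NF-kB genes were lower in inflamed UC than in pouchitis in each class, with few single members called. The immediate early list had an adjusted p of 1.4e-12 in T cells, 1.1e-12 in B cells, 9.5e-14 in plasma cells and 3.2e-15 in myeloid cells, each with adjusted p = 0.12 with an estimated correlation. Over all genes 0 of 26 members fell in B cells, 1 of 26 in plasma cells and 0 of 27 in myeloid cells. In T cells 2 of 27 members fell, NR4A1 (-0.92, adjusted p = 0.024) and IER5 (-0.67, adjusted p = 0.026); JUND had -0.49 (adjusted p = 0.055). The NF-kB list had an adjusted p of 4.9e-07 in T cells, 2.5e-09 in B cells, 2.7e-04 in plasma cells and 0.0039 in myeloid cells (adjusted p = 0.12, 0.12, 0.39 and 0.45 with an estimated correlation). It turned in direction in myeloid cells without doublet-like cells. In T cells 3 of 18 members fell, among them NFKBIE (-0.78, adjusted p = 0.017) and BCL2A1 (-1.16, adjusted p = 0.018), and 0 fell in the other classes. The interferon list was lower in T cells (adjusted p = 4.7e-05; adjusted p = 0.19 with an estimated correlation), and there IFIT2 (-1.28, adjusted p = 0.0095) and IFI44L (-1.07, adjusted p = 0.014) fell. It was lower in plasma cells (adjusted p = 0.025; adjusted p = 0.45 with an estimated correlation), where it turned in direction without doublet-like cells.

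In B cells 2 of 9763 genes were called. MT-ND6, a mitochondrial transcript, was at 154 ± 28.3 against 82.2 ± 25.8 CPM (edgeR adjusted p = 0.022; higher in 11 of 11 libraries). CCR9, named after its values were seen, had a log2 fold change of -2.91 (SE 0.51; adjusted p = 0.022). The MHC class II list was lower (adjusted p = 0.0015; adjusted p = 0.39 with an estimated correlation). In plasma cells 29 of 9305 genes were called, 15 higher and 14 lower. PRDX4, a peroxiredoxin of the endoplasmic reticulum, stood at 710 ± 251 against 370 ± 92.7 CPM (edgeR adjusted p = 0.029), CAV1 rose by a log2 fold change of 1.36 (adjusted p = 0.033) and SMAP2 by 0.98 (adjusted p = 0.017). CD69 (-1.38, adjusted p = 0.018), LDLRAD4 (-1.12, adjusted p = 0.038), INTS6 (-0.96, adjusted p = 0.043) and JUND (-0.66, adjusted p = 0.029) fell. All of these plasma cell genes lay on 1 side of the pouchitis mean in 11 of 11 libraries. The unfolded protein response list was higher (adjusted p = 0.012; adjusted p = 0.55 with an estimated correlation), with XBP1 at 0.38 (adjusted p = 0.30).

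In myeloid cells 11 of 7381 genes were called, 6 higher and 5 lower (n = 10 and n = 10). CXCL5 stood at 123 ± 179 against 2.89 ± 8.79 CPM (log2 fold change 6.52, SE 1.22; edgeR adjusted p = 0.030), higher in 6 of 10 libraries. It was the 1 inflammatory monocyte gene of 31 that rose (list adjusted p = 2.6e-04; adjusted p = 0.47 with an estimated correlation). CD163 stood at 121 ± 99.6 against 31.9 ± 17.7 CPM (adjusted p = 0.037), higher in 10 of 10 libraries, and APOE had 2.57 (adjusted p = 0.060). The resident macrophage list was higher (adjusted p = 0.040; adjusted p = 0.66 with an estimated correlation) but turned in direction without doublet-like cells. The carboxypeptidase gene CPM rose by a log2 fold change of 1.84 (adjusted p = 0.030), and CD1D (-1.45, adjusted p = 0.030), PSMB10 (-0.90, adjusted p = 0.030) and ARRDC1 (-0.92, adjusted p = 0.033) fell. The dendritic cell list was lower (adjusted p = 0.011; adjusted p = 0.24 with an estimated correlation). CD207, a marker of dendritic cells, fell by 2.70 on the log2 scale (adjusted p = 0.033) and CD1C had -1.59 (adjusted p = 0.056). The MHC class II list was lower too (adjusted p = 1.8e-05; adjusted p = 0.18 with an estimated correlation), with IFI30 at -0.59 (adjusted p = 0.16). VCAN (1.23), S100A8 (0.87), S100A9 (1.08), C1QA (0.60), IL1B (-0.00) and LYZ (-0.04) had adjusted p-values of at least 0.16.

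Among the 23 libraries of the larger gene table plasma cell calls fell to 1 and B cell calls to 1, and with the gene table as a covariate myeloid calls fell to 0. In T cells the calls of LEF1, MAL, TSHZ2 and HAVCR2 were lost among these 23 libraries (adjusted p = 0.060, 0.074, 0.066 and 0.070), as were those of the naive and central memory list (adjusted p = 0.067) and the red cell list (adjusted p = 0.10). So were those of the 7 called plasma cell genes named above and of CXCL5 and ARRDC1 in myeloid cells (adjusted p = 0.055 and 0.054). Without 1 library the calls ranged from 143 to 299 in T cells, from 0 to 4 in B cells, from 1 to 59 in plasma cells and from 0 to 133 in myeloid cells.

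**Figure D3:**
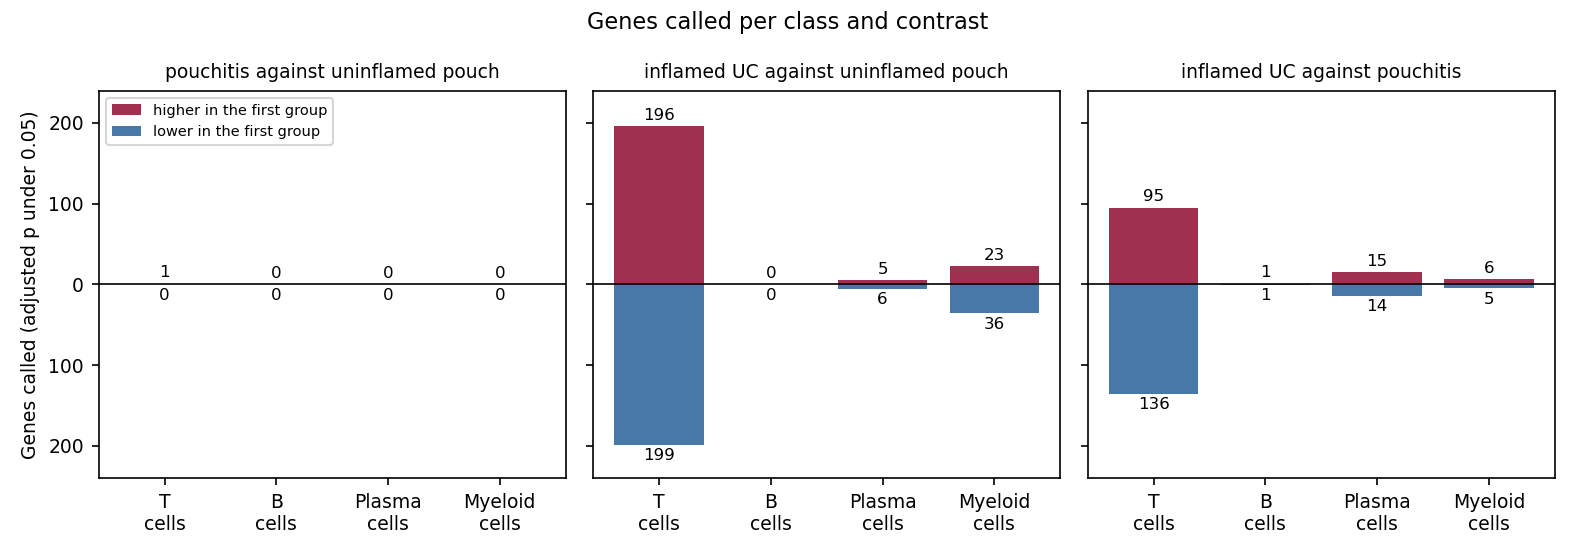
Genes called at an adjusted p under 0.05 by edgeR (y axis: number of genes, higher in the first group above 0 and lower below it) in each cell class (x axis), 1 panel per contrast. Most calls were in T cells of inflamed UC, 395 against the uninflamed pouch and 231 against pouchitis.

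Lists of other cell types and states were tested alongside. The smallest adjusted p over all contrasts and classes was 0.087 for epithelial markers and 0.20 for stromal markers (5 and 3 tested genes, in T cells). It was 0.18 for mitochondrial transcripts, 0.17 for naive B cell genes, 0.54 for memory B cell genes and 0.44 for plasmablast genes. The neutrophil and mast cell list had too few tested members, and the IgG, IgA and IgM lists were not comparable between groups, as were IGHG1, IGHA1 and IGHD.

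**Figure D4:**
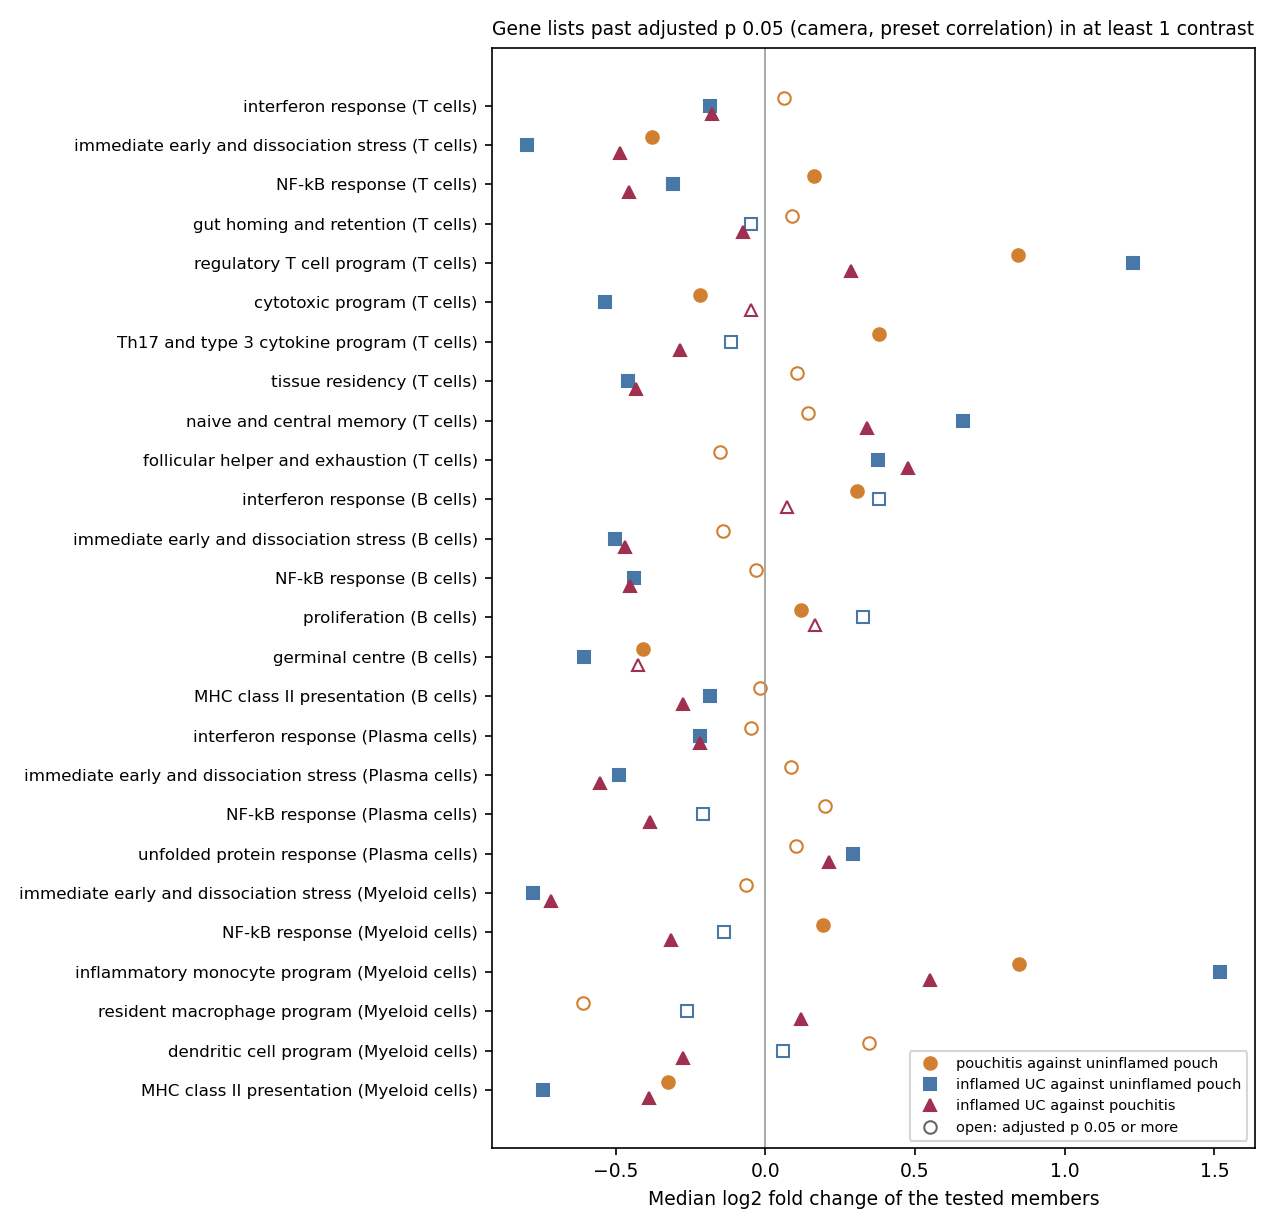
Median log2 fold change of the tested members (x axis) of each gene list past an adjusted p of 0.05 (camera, preset correlation) in at least 1 contrast (y axis: list and class; red cells not drawn); shapes mark the contrasts and open symbols an adjusted p of 0.05 or more. The regulatory T cell list had medians of 0.84 and 1.23 against the uninflamed pouch, and the immediate early list a median of -0.80 in T cells of inflamed UC.

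The 2 contrasts against the uninflamed pouch share its 5 libraries, so that their fold changes are tied in part by design. FOXP3 in T cells was the 1 gene called in the same direction in both. Independent lists would give 0.018, but these lists share their controls. Simulated groups without a change shared 0, but hardly any gene can be called in them. Neither value bears on the 1 shared gene. With the control libraries split between the contrasts no gene was shared, since FOXP3 was then not called in pouchitis. The covariance of the fold changes over genes of at least 20 CPM was 0.0390 in T cells against 0.0228 in simulations without a change. It was 0.0901 against 0.0479 in B cells, 0.0545 against 0.0359 in plasma cells and 0.356 against 0.105 in myeloid cells. The correlation was below that of the simulations in T cells (0.622 against 0.669) and plasma cells (0.631 against 0.696), and above it in B cells (0.712 against 0.674) and myeloid cells (0.87 against 0.775). The percent of genes with the same sign was 70.9 against 73.1 in T cells, 72.7 against 72.9 in B cells, 70.97 against 73.9 in plasma cells and 79.6 against 78.6 in myeloid cells. With the control libraries split, where no change gives about 0, the 2 covariances were 0.0335 and 0.0201 in T cells and 0.0662 and 0.0896 in B cells. They were 0.0397 and 0.00661 in plasma cells and 0.294 and 0.324 in myeloid cells. In the second split of plasma cells 46.1% of genes had the same sign. Genes are not independent replicates.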

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

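The tests of the mix of T cell populations, gene tables and depth for T cell genes, of depth, gene tables and the whole-cause test for FOXP3, of depth in B, plasma and myeloid cells for the stress list, and the splits of libraries for the gene calls of both contrasts against the uninflamed pouch were chosen only after the result was seen; the limits for a library that stands apart were fixed before the data were examined.

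In 6 of 51 groups of shares and 30 of 210 groups of gene levels 1 library stood apart from its group, 11.8% and 14.3%. The limits give about 1 in 20 by chance only for normally distributed values. Percents and CPM were tested without a log scale, and each library that stood apart was the highest of its group. The 1 in 20 need not hold here, so these percents do not show an excess of unusual libraries. Groups of 11 libraries, among them all shares of inflamed UC, were not tested. The values given next are the gap to the nearest library divided by the range of the group. In 1 pouchitis library B cells made up 78.7% of cells against a median of 18.6% in the others (0.656), and its group's highest follicular_cells share was 73.2% against 16.1% (0.744). NK_cells reached 4.09% against 0.892% (0.476) and mono_mac1 3.72% against 0.910% (0.506) in pouchitis, and Tfh_cells 9.87% against 4.82% (0.828) and mast_cells 6.28% against 0.494% (0.876) in the uninflamed pouch. CXCL10 in B cells of pouchitis reached 107 CPM against a median of 3.59 (0.93).

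In myeloid cells APOE stood apart in 1 library of each group (0.558 in inflamed UC, 0.668 in pouchitis, 0.864 in the uninflamed pouch). In inflamed UC so did CD1C (0.469), CD1D (0.509) and S100A9, at 8803 CPM against a median of 1826 (0.586). CXCL5 reached 27.9 CPM in 1 pouchitis library against a median of 0 (0.963). Among the 4 uninflamed pouch libraries 1 stood high for each of CD207 (0.91), HLA-DRA (0.922), HS3ST3B1 (1, its single count), HSPE1 (0.885), INHBA (0.935) and PSMB10 (0.854). It was not the same library for all of these genes. LDLRAD4 in plasma cells of the uninflamed pouch had 0.747.

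In T cells of the uninflamed pouch CCL3L1 reached 1662 CPM against a median of 36.9 (0.941), CXCL13 100.7 against 2.31 (0.806) and IL2 487 against 105 (0.728), with CTSH at 0.74 and IFI44L at 0.733. In pouchitis T cells IL2 reached 1058 CPM against 87.8 (0.741), XCL1 1358 against 107 (0.604) and CCL3L1 950 against 50.3 (0.874), and the gaps were 0.525 for CTSH, 0.53 for HAVCR2, 0.503 for IFI44L, 0.52 for IFIT2, 0.524 for IL17A, 0.541 for IL1R1 and 0.468 for NFKBIE. Of the UMIs of the 3 libraries with the smaller set of symbols, 17.078% lay on genes that no comparison used, most of them absent from the other table.

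T cells of inflamed UC differed from those of the uninflamed pouch in 395 genes. In 10 of 10 populations fitted the called genes kept at least 0.5 of their median change, with ratios from 0.576 to 1.02. That would argue against a different mix of T cell populations as the whole cause if each population's counts came from its own cells. Free RNA could not be removed and carries a changed mix into every population, and the genes were called in these same libraries. A different mix therefore cannot be excluded, and naive_CD8 was not among the populations fitted. The gene tables and depth are argued against as the whole cause. A count of 206 genes was called within the larger table, against at most 16 in 99 other splits of those libraries. With depth as a covariate 301 were called, against at most 6 in 99 other splits fitted in the same way. Of 100 splits of the libraries only the real one gave as many calls (highest other 27), which argues against chance. Whether the diagnosis or the tissue, rectum against ileal pouch, underlies the difference was not tested, since they changed together; CCR9, a small intestinal homing receptor, was among the called genes.

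FOXP3 was higher in pouchitis T cells by a log2 fold change of 1.65 (SE 0.29). Foxp3_cells made up 13.3% ± 3.33 of the T cells of a library in pouchitis (SD, n = 10) and 6.65% ± 1.07 in the uninflamed pouch (n = 5). This larger share may account for much of the FOXP3 change, since within Foxp3_cells the change was 0.70 (SE 0.17), under 0.5 of the whole. The larger share is argued against as the whole cause, since that change within Foxp3_cells was over 2 SE above 0. Cells assigned to the wrong population were not tested. FOXP3 counts outside Foxp3_cells were not read as expression, since free RNA could not be removed. Depth and gene tables are argued against as causes of the fold change, which was 1.58 (SE 0.31) with depth as a covariate and 1.76 (SE 0.31) within the larger table, where the call itself was lost. In 7 of 100 splits of the libraries as many genes were called (1 in the real split, at most 23 in the others), so chance cannot be excluded for the count.

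The immediate early and stress list was lower in inflamed UC. Depth per cell as the whole cause is argued against in 3 classes. The median of the list against the uninflamed pouch was -0.73 with depth as a covariate and -0.80 without in T cells, -0.43 and -0.49 in plasma cells, and -0.80 and -0.78 in myeloid cells. In B cells it was -0.37 and -0.50, between the bounds set, so that there depth and a difference in expression cannot be told apart. Against pouchitis the B cell median was -0.44 with depth as a covariate and -0.47 without, with 25 of 26 members lower in both. Handling that acts on a whole library, such as the time between biopsy and freezing, could lower these genes in all classes at once. After removing group means the list's level in T cells correlated across 26 libraries with that in B cells (r = 0.683, permutation p = 4.5e-04, adjusted p = 6.7e-04; rho = 0.602, permutation p = 0.00281; r = 0.582 without the 2 farthest libraries). It correlated less with that in plasma cells (r = 0.47, permutation p = 0.0232; rho = 0.411, permutation p = 0.0424; 0.241 without the 2 farthest, on which the relation rests). With myeloid cells (24 libraries) r was 0.816 at the smallest permutation p possible, 1e-05 (rho = 0.773, permutation p = 6.0e-05; 0.763 without the 2 farthest). The smaller of the first 2 lay between the bounds set for and against it, so that handling and a difference in cell activation cannot be told apart.

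For the other counts of genes, the splits as large as the real one out of 100, with the real count and the highest other, were as follows. Against the uninflamed pouch chance was unlikely for inflamed UC in plasma cells (1 split, 11 genes, highest other 7). In myeloid cells 2 splits gave as many as the real 59 genes, and the other one gave more, 77, so chance cannot be excluded there. For inflamed UC against pouchitis chance was unlikely in T cells (1 split, 231 genes, highest other 32) and plasma cells (1 split, 29 genes, highest other 4). In myeloid cells only the real split gave as many, but with 11 genes against a highest other of 10. Leaving out 1 library gave 0 to 133 myeloid calls there, so chance cannot be excluded. In B cells it cannot be excluded either (5 splits, 2 genes, highest other 201). Where 0 genes were called all 100 splits gave as many: pouchitis in B cells (highest other 403), plasma cells (2) and myeloid cells (3), and inflamed UC in B cells (3). The source of the splits of B cells with 403 and 201 genes was not tested. For the gene lists chance cannot be excluded in pouchitis (53 splits, 11 lists, highest other 16). Nor can it in inflamed UC against the uninflamed pouch (19 splits, 18 lists, highest other 22). In inflamed UC against pouchitis 3 splits gave as many (23 lists, highest other 23), which makes chance less likely but does not exclude it. The median of the other splits was 11, 14 and 12 lists in the same order. The list p-values at the preset correlation are therefore too small.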

How the results depend on the processing

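The settings on gene tables, earlier forms of the rule for leaving out genes, the cycling population and limma were chosen after seeing the data; the others were planned. Except where a setting itself takes away libraries, cells or genes, the cause of a change was not tested.

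Called genes in T cells, pouchitis against the uninflamed pouch (1): 0 with the depth covariate, without doublet-like cells, in the most abundant population, with gene tables as deposited, in the larger gene table alone, with the table as covariate and with only the 2 groups. Leaving out 1 library gave 0 to 1. Inflamed UC against the uninflamed pouch (395): 110 with the replicate block (102 shared), 128 in the most abundant population, 256 with tables as deposited, 206 in the larger table (184 shared), 655 by DESeq2; 130 to 559 without 1 library. Inflamed UC against pouchitis (231): 136 with the block, 123 in the most abundant population, 385 by DESeq2; 143 to 299 without 1 library.

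Called genes in B cells, pouchitis (0): 5 by DESeq2; 0 without any 1 library. Inflamed UC against the uninflamed pouch (0): 1 in the most abundant population, 2 with the table covariate, 2 with only the 2 groups, 10 by DESeq2; 0 to 2 without 1 library. Against pouchitis (2): 6 with the depth covariate, 1 in the most abundant population, in the larger table, with the table covariate and by limma, and 0 with the block, without doublet-like cells, without the cycling population and with only the 2 groups; 0 to 4 without 1 library.

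Plasma cells, pouchitis (0): 1 by DESeq2; 0 to 1 without 1 library. Inflamed UC against the uninflamed pouch (11): 3 with the block, 24 with the depth covariate, 24 without doublet-like cells, 2 in the larger table, 18 with the table covariate, 21 with only the 2 groups, 110 by DESeq2; 1 to 34 without 1 library. Against pouchitis (29): 2 with the block, 4 without doublet-like cells, 7 with tables as deposited, 1 in the larger table, 12 with the table covariate, 89 by DESeq2, 10 by limma; 1 to 59 without 1 library.

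Myeloid cells, pouchitis (0): 3 without the low-count filter, 4 without doublet-like cells, 7 by limma; 0 without any 1 library. Inflamed UC against the uninflamed pouch (59): 14 with the block, 109 with the depth covariate, 347 without doublet-like cells, 187 in the most abundant population, 32 with tables as deposited, 39 under form 2 of the rule, 3 in the larger table, 22 with the table covariate, 269 by DESeq2, 214 by limma; 2 to 256 without 1 library. Against pouchitis (11): 18 without the filter, 25 with the block, 2 with at least 50 cells, 6 with tables as deposited, 0 with the table covariate and with only the 2 groups, 141 by DESeq2, 1 by limma; 0 to 133 without 1 library. With at least 50 cells per library no uninflamed pouch library was left, so that setting was not run for 2 contrasts.

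Shares past the threshold, pouchitis (0): 6 on the logit scale, 1 as percent of the class; 0 to 3 without 1 library. Inflamed UC against the uninflamed pouch (2): 6 on the logit scale, 1 without doublet-like cells, 0 without plasma cells in the denominator and 0 in the larger table; 0 to 3 without 1 library. Against pouchitis (2): 1 on the logit scale. Lists past the threshold, pouchitis (11): 1 with an estimated correlation, 11 with the block (8 shared), 5 in the most abundant population; 5 to 14 without 1 library. Of 10 lists of B cells 3 passed without the cycling population, 2 of them among the 3 called with it. With an estimated correlation 0 of 18 and 0 of 23 lists of the other contrasts passed. The gene shared by both contrasts (1) was lost, 0, with the controls split.

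List tests that turned in direction, with adjusted p: proliferation in B cells in pouchitis, 8.0e-09 without doublet-like cells, 0.695 in the most abundant population and 0.937 without 1 of the uninflamed pouch libraries (leaving out any other kept the direction, and over all of these fits p was 1.1e-07 to 0.937); follicular helper and exhaustion, most abundant population, 0.630 against the uninflamed pouch and 0.849 against pouchitis; inflamed UC against pouchitis without doublet-like cells, interferon in plasma cells 0.988, NF-kB in myeloid cells 0.832 and resident macrophages 0.787. Of the other values for single lists 485 kept their direction and side of the threshold and 78 were lost; for single genes 2435 kept them, 196 were lost and 30 gained; for single shares 32, 8 and 7. Without 1 library 867 list values kept them and 64 were lost, 2319 gene values kept them, 256 were lost and 35 gained, and for shares the numbers were 154, 16 and 8.

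Depth limits myeloid cells of the uninflamed pouch most, with 171 cells in all. The replicate numbers showed no sign of pairing libraries in T cells. Sex-linked, HLA, immunoglobulin and T cell receptor genes were left out there. The residuals of 4 of 20 same-numbered pairs correlated by over 0.1, with a mean of -0.0512 against 0.00582 for other pairs. Of 25 libraries 1 correlated best with a same-numbered one. A shared donor need not show in this test, so pairing cannot be excluded.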

Other observations

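Other populations were set apart by their own genes. Plasma cells fell into plasma_NFKBIA_hi (4568 cells) and plasma_NFKBIA_lo (2639 cells), whose top genes include SDC1, MZB1 and JCHAIN; they averaged 10.97% ± 6.27 and 6.06% ± 3.52 of cells in inflamed UC (SD, n = 11), 7.89% ± 5.81 and 4.83% ± 3.75 in pouchitis (n = 10) and 6.73% ± 5.18 and 3.93% ± 2.82 in the uninflamed pouch (n = 5). Germinal centre cells, with SERPINA9 and RGS13 among their top genes, averaged 2.05% ± 3.39, 2.50% ± 2.56 and 3.50% ± 3.33 in the same order. Cells of mono_mac3, with the complement genes C1QA, C1QB and C1QC, averaged 0.858% ± 0.819, 0.787% ± 0.469 and 0.152% ± 0.141. Plasmacytoid dendritic cells (75 cells, with LILRA4 and CLEC4C) were found in 9 of 11 inflamed UC libraries, 7 of 10 pouchitis libraries and 0 of 5 uninflamed pouch libraries. As 0 of 16878 pooled cells of the uninflamed pouch, this allows a share of up to 0.0178% in that pool. Libraries and not cells are the replicates, so other uninflamed pouches may hold more. None of these shares passed the corrected permutation test.

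Th17_cells, with IL17A and IL23R, averaged 5.34% ± 2.81 in inflamed UC, 7.04% ± 3.12 in pouchitis and 7.44% ± 3.63 in the uninflamed pouch. NK_cells, with KLRF1 and GNLY, averaged 1.18% ± 0.768, 1.499% ± 1.19 and 1.48% ± 0.551. The population that the authors named mast_cells averaged 2.13% ± 2.17, 0.951% ± 0.574 and 1.73% ± 2.56. Its top 10 genes held the mast cell genes TPSAB1, CPA3, CTSG and GATA2 and, in larger number, COL3A1, CXCL14, POSTN, IGFBP5, LUM and COL1A2, genes of stromal cells. HBB, a red cell gene, was among the top genes of memory_CD4 and of plasma_NFKBIA_hi. Cells of activated_CD4 and mono_mac1 were shallow, with medians of 1575 and 1292 UMIs.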
